A study of Mus musculus with 16 samples.

How the data were processed

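Striatal RNA from 16 mice (2 strains, control or risperidone, 4 biological replicates per group) was measured on Affymetrix mouse expression arrays (perfect-match design), with 1 array per mouse. Per the labels, the authors normalized the arrays with RMA (version not stated), and the deposited values are log2 expression levels per probe set with 2 decimals. Other upstream steps (scanning, software, array filters) are not stated. The values were used on that log2 scale without further transformation, after checking that the array medians and quartiles were nearly equal. Of 45141 probe sets, 104 array controls were left out and 45037 were tested, with no filter on low levels. Of these, 28898 name 1 gene, 551 name several and 15588 name none; probe sets naming several or no genes were tested but not assigned to a gene. Gene names came from the platform's annotation, and 28689 named probe sets matched the GRCm38.p6 reference by Entrez ID, with 0 symbols changed.

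A linear model with the 4 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and figures were drawn with matplotlib 3.10.9. The 6 comparisons were risperidone minus control in A/J and in DBA/2J, the mean of both effects, the DBA/2J effect minus the A/J effect (interaction), and DBA/2J minus A/J in control and in risperidone mice. All tests were two-sided. P values were adjusted by Benjamini-Hochberg over all 45037 probe sets within a comparison, and a gene was called where at least 1 probe set naming it alone had an adjusted p under 0.05. A gene's values are those of its probe set with the highest mean over all arrays. SE is that of limma's difference and SD is that of the 4 arrays of a group. Replicate numbers were not used as pairs. Of the 4 correlations between same-numbered arrays computed in each of 4 comparisons, 1 or 2 exceeded 0.1, and 8 of 16 arrays correlated best with their own number. The mean correlation of same-numbered arrays was 0.049, 0.074, 0.056 and 0.025. That of arrays with other numbers was lower, at -0.016, -0.025, -0.020 and -0.008. A small effect shared by arrays of 1 number is therefore not excluded, and a fit with the number as a block was run as an alternative.

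Gene lists (29 lists with 598 entries, 516 matched) covered signalling pathways, stress and metabolic responses, striatal and other brain cell types, neighbouring regions, blood, and checks of the strain and sex labels. Each was tested with camera from limma with its preset correlation of 0.01 and again with a correlation estimated from the data; p was adjusted over the 29 lists within a comparison. A list's value is the median log2 difference of its members. Counts adjusted over the list alone use Benjamini-Hochberg over the list's members. The mean level of a list was compared between 2 groups of arrays by an exact permutation test, for which 0.0286 is the smallest two-sided p with 4 against 4 arrays.

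The comparisons, tests, lists, alternative settings and the rule for named genes were chosen before the data were examined. The rule names, for each comparison, the 10 highest and 10 lowest called genes whose groups do not overlap, the 10 genes with the smallest p where fewer than 10 passed in a risperidone comparison or the interaction, up to 4 members of a list with the smallest p, and a fixed set (Gpnmb, Klrd1, Myo5a, Dysf, Drd2, Drd1, Adora2a, Penk, Pdyn, Tac1, Nts, Fos, Htr2a, Mtor). Some list members named beside their list, such as Mag, Ttr and Gfap, are there for their known role.

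The DBA/2J share of each array was computed after the arrays had been examined. It is the median, over strain marker probe sets, of the position of the array's unlogged value between the means of the A/J and the DBA/2J control arrays, with control arrays scored by markers and means chosen without them. Markers had an absolute log2 difference of at least 1.5 between strains in control mice, a level of at least 7 in the higher strain and an adjusted p under 0.01; there were 49 over all control arrays, of which 26 were higher in DBA/2J and 23 higher in A/J, and 8 are from Pisd, Pisd-ps3 or Sfi1. Intervals are 95% bootstrap intervals over markers.

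Other settings chosen beforehand were a second quantile normalization, median centring, a filter at the median level, 1 probe set per gene, eBayes with trend and robust options, array weights, replicate number as a block, at least 1.2-fold, only the 8 arrays compared, leaving out each of 16 arrays in turn, an estimated correlation in camera, and the mean of a gene's probe sets. Settings added after seeing the data were the DBA/2J share as a covariate, 3 regional marker scores as covariates, leaving out 3 or 5 arrays in doubt (either leaves 1 A/J risperidone array), and leaving out probe sets called for strain. The 3 regional scores were the mean levels of striatal projection neuron markers, of choroid plexus and ependyma markers, and of thalamus markers. Cortex markers were not among them. In 20 draws of simulated data with the same design, the model called a median of 78% of 1.5-fold changes (68% to 86%) and 98% of 2-fold changes (96% to 100%), and a median of 5.81% of calls were false (2.76% to 9.38%). The changed probe sets were drawn from those above the median level. Many more were changed per draw than were called in any risperidone comparison, which makes the adjusted p threshold easier to pass. The percentages called therefore do not apply to a comparison with few changes, such as risperidone in A/J. The noise was independent between probe sets, and no array was outlying or mixed. More changes can therefore be missed, and more calls be false, in the real data. With nothing changed, 1 probe set was called in 3 of the draws and none in the rest. A simulated share of 30% was recovered as 24.1% to 37.3%. Random splits (35 or 100 per comparison) and 10000 random lists were drawn with fixed seeds. All per-sample values were used.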

Results

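Total RNA from the striatum of 16 male mice was measured on Affymetrix mouse expression arrays. The mice came from 2 inbred strains, A/J and DBA/2J, and were 7 to 8 weeks old. In each strain 4 mice were given risperidone, an antipsychotic that blocks dopamine D2 and serotonin 5-HT2A receptors, at 1 mg/kg once daily for 3 days. The other 4 mice of each strain are labelled untreated, while the protocol shared by all samples names saline injections; they are called control mice here. Each array held 45037 probe sets after array controls were removed, and 17097 genes were named by at least 1 probe set of their own. Array medians lay between 5.66 and 5.71 on the log2 scale. The precision of every value is limited by the number of arrays, 4 per group.

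The arrays were first described by genes that tell the strains or the tissue apart. In control mice, the share of DBA/2J signal lay between -3.66% and 1.13% in A/J and between 96.0% and 102.382% in DBA/2J. Each control array was scored over 46 to 49 strain marker probe sets chosen without it, and each risperidone array over 49. Among the A/J risperidone arrays the share was 28.5% in replicate 1, 36.5% in replicate 2, 0.283% in replicate 3 and 39.7% in replicate 4. In the DBA/2J risperidone arrays it lay between 87.3% (replicate 1) and 101.954%. DBA/2J control replicate 4 stood apart from the rest. Its correlation with the other arrays lay between 0.970 and 0.979, and the mean log2 level of its ribosomal protein genes was 10.04 against 10.49 to 10.56 in the other 3 arrays of its group. Ttr, which encodes the transthyretin made by the choroid plexus, had log2 levels between 6.0 and 11.97 over the 16 arrays, and Tcf7l2, a transcription factor of thalamic neurons, between 5.81 and 8.98.

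**Figure D1:**
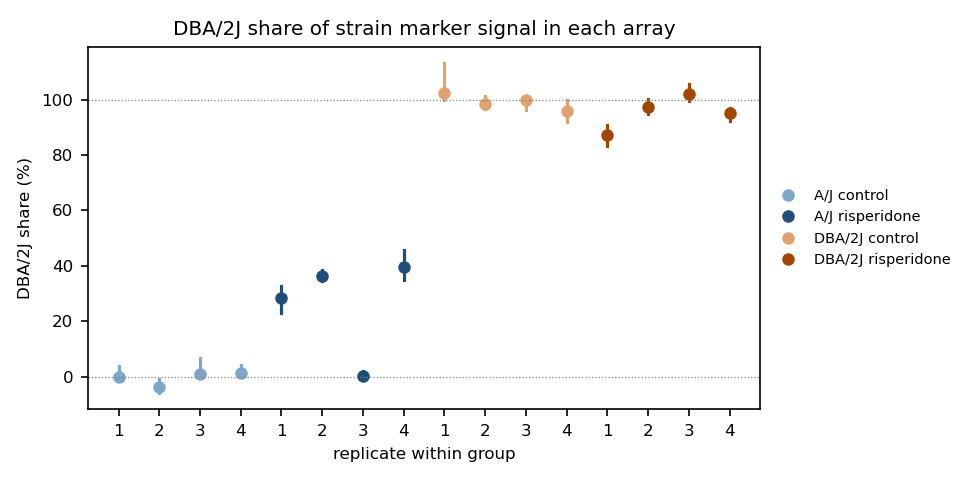
DBA/2J share of the strain marker signal (%, vertical axis) in each of the 16 arrays (replicate number, horizontal axis); points are medians over marker probe sets and bars are 95% bootstrap intervals. A/J risperidone replicates 1, 2 and 4 lie at 28.5%, 36.5% and 39.7%, between the A/J and the DBA/2J control arrays.

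The first question was which genes respond to risperidone in DBA/2J mice. Immediate early genes, which neurons switch on with activity, were lower after the drug. Egr2, a zinc finger transcription factor, fell 2.23-fold (log2 difference -1.16 ± 0.13 SE, n = 4 per group, adjusted p = 0.000862), from 8.94 ± 0.18 (SD) in control mice to 7.78 ± 0.26. Fos, a subunit of the AP-1 transcription factor, fell 1.75-fold (-0.81 ± 0.10, adjusted p = 0.00284), from 8.78 ± 0.14 to 7.97 ± 0.21. Ccn1, a matricellular protein gene, fell 1.82-fold (-0.86 ± 0.14, adjusted p = 0.0355), and Arc, which regulates AMPA receptor trafficking at synapses, fell 1.73-fold (-0.79 ± 0.13, adjusted p = 0.0367). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 1.76-fold (0.81 ± 0.13, adjusted p = 0.0367), from 6.59 ± 0.30 to 7.41 ± 0.23.

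With limma, 11 genes passed in DBA/2J, 2 higher and 9 lower, from 18 probe sets of which 6 name no gene; 4806 probe sets had an unadjusted two-sided p under 0.05, against 2251.85 expected by chance. Rassf3, Egr1, Dusp1 (a MAP kinase phosphatase) and Rell1 also fell, by 0.64, 0.64, 0.49 and 0.46 on the log2 scale, each at an adjusted p of 0.0367. The 2 remaining genes, Flrt2 (-0.59) and Hif3a (0.62), passed by a probe set other than the one with the highest mean and were chosen after their values were seen. All 11 genes differed in the same direction in A/J, while the called probe sets naming no gene did not all do so. Egr2 and Fos passed without each of the 16 arrays in turn, while the other 7 shown genes each missed without 9 to 14 of them, at adjusted p up to 0.197 and with no difference moved by over 1.5 times. The count was 7 without A/J control replicate 1, 2 or 4, 4 without A/J risperidone replicate 1, and 3 without A/J risperidone replicate 2, 3 or 4. It was 3, 2, 6 and 4 without DBA/2J control replicates 1, 2, 3 and 4, and 2, 27 and 3 without DBA/2J risperidone replicates 1, 2 and 3. Dusp1 and Rell1 missed with the replicate number as a block (adjusted p = 0.0693 and 0.0650, differences unchanged). With 3 regional marker scores as covariates the count was 1, with Fos at -0.72 ± 0.11 (adjusted p = 0.0975), and with the 8 DBA/2J arrays alone or without 5 arrays in doubt it was 0.

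Gene groups in DBA/2J moved as follows. Of 32 activity-regulated early genes measured, 27 were lower, with a median of -0.21 (camera, adjusted p = 3.9e-17; adjusted p = 0.0126 with an estimated correlation). Over all genes tested 6 of them fell, and adjusted over the list alone 14 fell and 1 rose. Nr4a1 (-0.66, adjusted p = 0.0956), Btg2 (-0.51, adjusted p = 0.113), Nptx2 (-0.48, adjusted p = 0.113) and Dusp6 (-0.40, adjusted p = 0.0738) did not pass over all genes. Dusp6 passed without DBA/2J risperidone replicate 2, at an adjusted p of 0.0346. Of 17 glucocorticoid-responsive genes 14 were higher (median 0.16, adjusted p = 0.000373; adjusted p = 0.732 with an estimated correlation). 1 of them, Fkbp5, rose over all genes, and adjusted over the list alone 4 rose; Plin4, a lipid droplet protein gene (0.62, adjusted p = 0.168), and Tsc22d3, an anti-inflammatory leucine zipper gene (0.49, adjusted p = 0.306), did not pass over all genes.

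Cytosolic ribosomal protein genes were higher as a list in DBA/2J after risperidone, in 62 of 63 members (median 0.16, adjusted p = 3.7e-11), and so were oxidative phosphorylation genes of the mitochondrial respiratory chain, in 43 of 44 (median 0.11, adjusted p = 2.5e-05). Examples are Rplp0, a protein of the ribosomal stalk (0.30, adjusted p = 0.382), and Cox6c, a cytochrome c oxidase subunit (0.32, adjusted p = 0.428), neither of which passed alone. Choroid plexus and ependyma markers had a median of 0.28 with 12 of 13 higher (adjusted p = 0.00237), among them Otx2 at 0.89 and Ttr at 1.99, and astrocyte markers a median of 0.15 with 13 of 15 higher (adjusted p = 0.0334). All 4 of these calls were lost with an estimated correlation, at adjusted p = 0.732 with an estimated correlation in each. No member of these lists passed over all genes, and adjusted over the list alone 2 choroid plexus markers rose. DBA/2J control replicate 4 had the lowest ribosomal and oxidative phosphorylation levels of its group, and without that array the medians were 0.04 (adjusted p = 0.0324) and 0.02 (adjusted p = 0.539). The choroid plexus call was lost without DBA/2J risperidone replicate 1 (median 0.06, adjusted p = 0.428), the array with a choroid plexus score of 5.88 against 4.75 to 4.93 in its group. The astrocyte call was lost without DBA/2J control replicate 1 (adjusted p = 0.0531), 2 (0.10) or 4 (0.0843) and without DBA/2J risperidone replicate 4 (0.314).

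**Figure D2:**
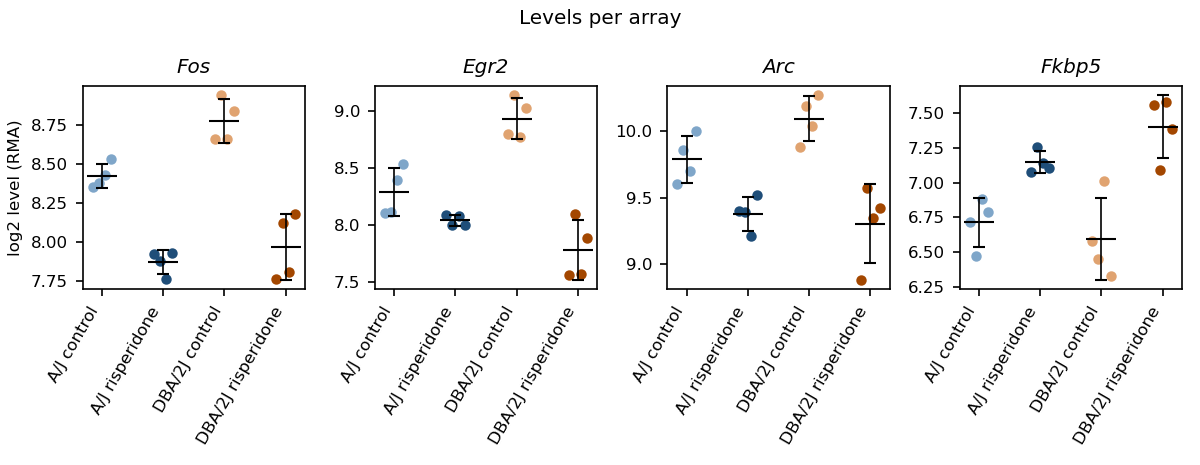
Log2 level (RMA, vertical axis) of Fos, Egr2, Arc and Fkbp5 in each of the 16 arrays by group (horizontal axis); points are arrays and lines are the mean ± SD of 4. In DBA/2J, mean Egr2 was 8.94 in control and 7.78 in risperidone mice, and mean Fkbp5 was 6.59 and 7.41.

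The same question was asked in A/J mice. The early genes Fos, Ccn1 and Klf2 were among the 4 genes with the smallest p, with lower values in risperidone mice, and did not pass. Fos had a log2 difference of -0.55 ± 0.10 (SE, n = 4 per group, adjusted p = 0.123), at 7.87 ± 0.08 (SD) against 8.42 ± 0.08 in control mice, Ccn1 one of -0.78 ± 0.14 (adjusted p = 0.119), and Klf2, a Krüppel-like transcription factor, one of -0.59 ± 0.10 (adjusted p = 0.0822). Klf2 was also lower in DBA/2J than in A/J control mice, so its value in A/J lay toward the DBA/2J level, and in DBA/2J its risperidone difference was 0.06. As a list, the activity-regulated early genes were lower in 25 of 32 members (median -0.15, adjusted p = 5.2e-08; adjusted p = 0.133 with an estimated correlation). None passed over all genes, and adjusted over the list alone 8 fell. The mean level of the list was lower in risperidone mice by an exact two-sided permutation test (p = 0.0286, the smallest that 4 against 4 arrays allow).

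With limma no gene passed in A/J (0 genes); 2483 probe sets had an unadjusted p under 0.05 against 2251.85 expected. Of the 10 genes with the smallest p, 7 also passed for strain in control mice (Klf2, Stab2, Nlrc3, Chchd4, Vmn2r29, Mertk and Fhdc1), and all 7 differed toward the DBA/2J level, as did the strain marker share of replicates 1, 2 and 4. Both comparisons use the same A/J control arrays, which alone favours agreement in direction among genes picked this way. Stab2, a scavenger receptor gene, was at 1.5 ± 0.29 (adjusted p = 0.165), Nlrc3 at 0.69 (adjusted p = 0.0871), Chchd4 at 0.56 (adjusted p = 0.138) and Vmn2r29 at 0.56 (adjusted p = 0.140). Mertk was at 0.42 (adjusted p = 0.237) and Fhdc1 at -0.35 (adjusted p = 0.236), and Tyms, not called for strain, at 0.38 (adjusted p = 0.250). Without A/J risperidone replicate 3, the array whose markers match A/J, 17 genes passed, among them Stab2 (adjusted p = 0.0089), Klf2 (0.0195) and Chchd4 (0.0199), and without DBA/2J risperidone replicate 1 the count was 1. It was 7 among probe sets above the median level and 12 with array weights.

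Cell type lists in A/J moved in both directions. Oligodendrocyte markers were lower in 16 of 16 members (median -0.14, adjusted p = 0.000495; adjusted p = 0.863 with an estimated correlation), among them the myelin genes Mog (-0.53, adjusted p = 0.695) and Mag (-0.44, adjusted p = 0.927). None passed over all genes or adjusted over the list alone, and the call was lost without A/J control replicate 3 (median -0.04, adjusted p = 0.380). With the strain marker share as a covariate the list's median was -0.14 (adjusted p = 0.0871), and over its alternatives the adjusted p ranged from 3.6e-07 to 0.900. Blood markers were higher in 4 of 5 (median 0.48, adjusted p = 0.000422; adjusted p = 0.133 with an estimated correlation), including the haemoglobin genes Hbb-b2 (0.66, adjusted p = 0.521) and Hba-a1 (0.65, adjusted p = 0.762), and adjusted over the list alone 3 rose. Glucocorticoid-responsive genes were higher in 12 of 17 (median 0.04, mean 0.14, adjusted p = 0.00133; adjusted p = 0.806 with an estimated correlation). None of them passed over all genes and adjusted over the list alone 4 rose. Their list call was lost without A/J control replicate 2 (adjusted p = 0.0681).

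The risperidone effect was then averaged over both strains, which does not test whether the strains share it. Fos fell by 0.68 ± 0.07 (SE, n = 4 per group, adjusted p = 0.000638) on the log2 scale, Ccn1 fell by 0.82 ± 0.10 (adjusted p = 0.00229) and Egr2 fell by 0.70 ± 0.09 (adjusted p = 0.0024), a mean of -1.16 in DBA/2J and -0.25 in A/J, where it did not pass. Arc fell by 0.60 (adjusted p = 0.0230), the antiproliferative gene Btg2 fell by 0.46 (adjusted p = 0.0252) and Dusp1 fell by 0.37 (adjusted p = 0.0250), while Fkbp5 rose by 0.62 ± 0.10 (adjusted p = 0.0224). Hif3a (0.51) and Rgs4 (-0.41), a regulator of G protein signalling, passed by a probe set other than the one with the highest mean and were chosen after their values were seen. Activity-regulated early genes were lower in 29 of 32 (median -0.19, adjusted p = 1.8e-24; adjusted p = 0.00269 with an estimated correlation). Over all genes 6 fell, and adjusted over the list alone 16 fell and 1 rose; 22 of the 32 were lower in each strain and 2 were higher in each.

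With limma 9 genes passed, 2 higher and 7 lower, and 3106 probe sets had an unadjusted p under 0.05. Rassf3 (-0.43, adjusted p = 0.0742), Plin4 (0.54, adjusted p = 0.0816) and Pcolce2 (0.35, adjusted p = 0.0816) did not pass. Fos, Ccn1 and Egr2 passed without each array in turn, and the other 4 shown genes missed without 7 to 9 of them, at adjusted p up to 0.0917. Btg2 and Dusp1 missed with the replicate number as a block (adjusted p = 0.0520 and 0.0559, differences unchanged). The count was 4 without A/J control replicate 2, A/J risperidone replicate 2 or DBA/2J control replicate 2, and 17 without A/J risperidone replicate 3. It was 5 without A/J risperidone replicate 4 or DBA/2J risperidone replicate 1, 3 or 4. With the strain marker share as a covariate it was 3, with Egr2 missing (-0.69 ± 0.11, adjusted p = 0.0606), and with 3 regional marker scores 2, with Ccn1 missing (-0.70 ± 0.11, adjusted p = 0.0698). Leaving out the 3 A/J risperidone arrays with intermediate strain markers, or 5 arrays in doubt, leaves 1 A/J risperidone array (replicate 3), and the spread then comes from the other groups. So fitted, 0 and 2 genes passed; Fos, Ccn1 and Egr2 missed in both, at adjusted p up to 0.103, 0.137 and 0.597, while their differences stayed within 1.5 times (without 5 arrays -0.69 ± 0.10, -0.84 ± 0.12 and -0.63 ± 0.13). Glucocorticoid-responsive genes were higher in 14 of 17 (median 0.12, adjusted p = 6.1e-07; adjusted p = 0.195 with an estimated correlation); 1 rose over all genes and 5 rose adjusted over the list alone.

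Ribosomal protein genes were higher over both strains in 59 of 63 (median 0.08, adjusted p = 2.2e-08; adjusted p = 0.863 with an estimated correlation). Choroid plexus and ependyma markers were higher in 13 of 13 (median 0.18, adjusted p = 0.00129; adjusted p = 0.804 with an estimated correlation) and blood markers in 4 of 5 (median 0.38, adjusted p = 0.00129; adjusted p = 0.195 with an estimated correlation). Oxidative phosphorylation genes were higher in 36 of 44 (median 0.04, adjusted p = 0.0396; adjusted p = 0.985 with an estimated correlation). Without DBA/2J control replicate 4, whose ribosomal and oxidative phosphorylation levels were low, the ribosomal median was 0.02 (adjusted p = 0.0473) and the oxidative phosphorylation median turned to -0.0067 (adjusted p = 0.677). The oxidative phosphorylation call was also lost without A/J control replicate 2 (adjusted p = 0.280) or 4 (0.0688), A/J risperidone replicate 4 (0.131), and DBA/2J risperidone replicate 2 (0.0559) or 4 (0.210). The choroid plexus call was lost without DBA/2J risperidone replicate 1 (adjusted p = 0.141).

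**Figure D3:**
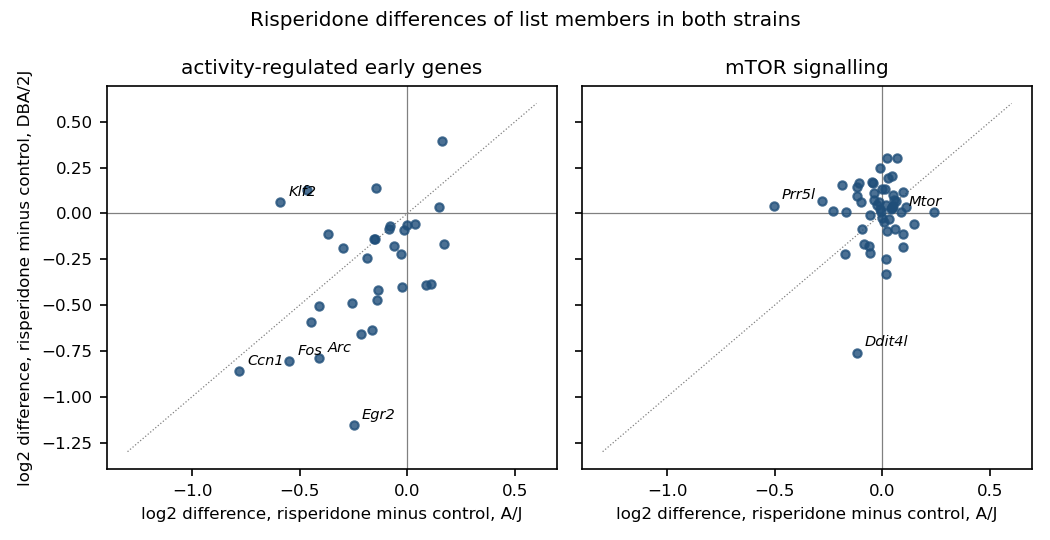
Log2 difference of risperidone minus control in A/J (horizontal axis) and in DBA/2J (vertical axis) for the 32 activity-regulated early genes and the 53 mTOR signalling genes measured; each point is a gene and the dotted line marks equal differences. Of the early genes 22 lie below 0 in both strains, and of the mTOR genes 7 lie below and 17 above 0 in both.

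The interaction asked whether the strains differ in their response. The gene with the lowest p was Hbegf, an epidermal growth factor receptor ligand, with a difference between the strains of 0.65 ± 0.12 (SE, n = 4 per group, adjusted p = 0.207). Egr2, called in DBA/2J and not in A/J, had a log2 difference of -0.91 ± 0.18 between the strains (adjusted p = 0.222), and Fos one of -0.26 ± 0.14 (adjusted p = 0.584). Klf2 had 0.65 (adjusted p = 0.235), Slc47a1, an organic cation exporter gene, -1.54 ± 0.32 (adjusted p = 0.235), and Tgfb2, a transforming growth factor gene, 0.91 (adjusted p = 0.280). With limma no gene passed (0 genes); 4140 probe sets had an unadjusted p under 0.05 against 2251.85 expected, and without A/J risperidone replicate 3 the count was 7. The others among the 10 smallest p were Scube1 at -0.55, Fbxo45 at 0.63, Plpp1 at 0.64, Zc3h6 at 0.70 and Ttc39c at 0.51.

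The response of 4 gene lists differed between the strains by camera with its preset correlation. Early genes were lower in DBA/2J relative to A/J (median -0.10, adjusted p = 0.00102), in 22 of 32 members, with 5 lower and 1 higher adjusted over the list alone. Ribosomal protein genes (median 0.15, 60 of 63 higher, adjusted p = 1.9e-05), oxidative phosphorylation genes (median 0.17, 41 of 44 higher, adjusted p = 5.5e-05) and oligodendrocyte markers (median 0.31, 15 of 16 higher, adjusted p = 0.00102) were higher. No member of these lists passed over all genes, and all 4 calls were lost, at adjusted p = 0.757 with an estimated correlation in each. Without DBA/2J control replicate 4 the ribosomal and oxidative phosphorylation calls were lost (medians 0.04 and 0.06, adjusted p = 0.380 and 0.128). The oligodendrocyte call was lost without A/J control replicate 3 (0.16, adjusted p = 0.0569) or DBA/2J risperidone replicate 4 (0.18, adjusted p = 0.126). With the strain marker share as a covariate the early gene median was -0.03 (adjusted p = 0.190), and over the 4 added alternatives its adjusted p ranged from 0.135 to 0.434.

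The title of the study names the mTOR pathway, which couples nutrients and growth factors to protein synthesis, so its members were tested as a list fixed beforehand. Of 64 entries 53 were measured. The list holds both promoting members, such as Rptor, and inhibitors, such as Ddit4l, so opposite changes can cancel in its median and test. RNA levels do not measure the activity of the pathway. Mtor itself had a log2 difference of 0.09 ± 0.07 (SE, n = 4 per group, adjusted p = 0.975) in A/J and 0.005 ± 0.07 (adjusted p = 0.985) in DBA/2J. In DBA/2J the lowest value was that of Ddit4l, an inhibitor of mTOR complex 1, at -0.76 ± 0.16 (adjusted p = 0.113). In A/J, Prr5l, a component of mTOR complex 2, was at -0.51 (adjusted p = 0.824) and Mapkap1, another, at -0.28 (adjusted p = 0.504).

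The list did not pass in any comparison. In A/J its median was 0.00 and its mean -0.02, with 26 members higher and 25 lower (adjusted p = 0.741; adjusted p = 0.863 with an estimated correlation). In DBA/2J the median was 0.04 with 36 higher and 17 lower (adjusted p = 0.823), over both strains 0.01 with a mean of -0.01 (adjusted p = 0.967), and for the interaction 0.02 with 30 higher and 22 lower (adjusted p = 0.666). No member passed in the risperidone comparisons over all genes (0 genes by limma), and adjusted over the list alone Ddit4l fell in DBA/2J. Without DBA/2J risperidone replicate 2, Ddit4l passed over all genes at an adjusted p of 0.0252. Its interaction value was -0.64 (adjusted p = 0.441). Other members with small p in DBA/2J were Prr5 at 0.30 (adjusted p = 0.367), Akt2 at -0.33 (adjusted p = 0.380) and Rptor, the scaffold of mTOR complex 1, at -0.18 (adjusted p = 0.444). Between the strains the list's adjusted p was 0.715 in control and 0.896 in risperidone mice, where the median was 0.02 and the test pointed down.

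Genes of striatal neurons, on which D2 receptor blockers act, did not pass over all genes after risperidone. In DBA/2J, Tac1, the substance P precursor of direct-pathway neurons, was at 0.83 ± 0.23 (SE, n = 4 per group, adjusted p = 0.218), and Drd2, the dopamine D2 receptor gene, at 0.56 ± 0.20 (adjusted p = 0.328). Without DBA/2J risperidone replicate 4, which had a dopamine signalling score of 7.40 against 6.96 to 7.01 in its group, Drd2 was at 0.35 (adjusted p = 0.531). Penk, the enkephalin precursor of indirect-pathway neurons, was at 0.48 (adjusted p = 0.526) and without DBA/2J risperidone replicate 1 at 0.28 (adjusted p = 0.758), Drd1 at 0.12 (adjusted p = 0.725), Pdyn at -0.04 (adjusted p = 0.900) and Nts at 0.02 (adjusted p = 0.972). In A/J, Drd2 was at -0.21 (adjusted p = 0.987), Drd1 at -0.16 (adjusted p = 0.967), Penk at -0.15 (adjusted p = 0.997), Tac1 at 0.27 (adjusted p = 0.982), Pdyn at -0.04 (adjusted p = 0.997) and Nts at 0.19 (adjusted p = 0.959). The interaction was 0.77 ± 0.28 for Drd2 (adjusted p = 0.441), 0.56 for Tac1 (adjusted p = 0.593) and 0.63 for Penk (adjusted p = 0.615). Adjusted over the list alone, 1 indirect-pathway marker (Drd2), 1 direct-pathway marker (Tac1) and 1 interneuron marker (Calb2, 0.87) were higher in DBA/2J, as were Tac1 over both strains and Drd2 in the interaction, and none in A/J. Mean Drd2 levels by group lay between 3.72 and 4.28, under the lower quartile of every array (4.46 to 4.60), and were not shown to be above background. Adora2a and Htr2a were not analysed here.

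Of 29 lists, 18 passed in none of the 6 comparisons. Their smallest adjusted p was 0.0510 for circadian clock genes (strain in risperidone mice, median -0.14), 0.0589 for striatal projection neuron markers (strain in control mice, -0.10) and 0.105 for cholesterol and lipid synthesis genes (risperidone in A/J, -0.045). It was 0.134 for vascular cell markers, 0.142 for GABA signalling, 0.207 for cortex markers, 0.266 for striatal interneuron markers, 0.316 for interferon response and MHC class I genes and 0.419 for serotonin signalling. It was 0.486 for neuropeptides, 0.531 for direct-pathway neuron markers, 0.715 for mTOR signalling and 0.896 for glutamate signalling. It was 0.722 for indirect-pathway neuron markers, oligodendrocyte precursor markers, chaperones and unfolded protein response genes and the genes that check the sex label, and 0.0589 for those that check the strain label.

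The strains were compared in control mice to ask which genes differ before the drug. Pdxdc1 was higher in DBA/2J (log2 difference 3.21 ± 0.34 SE, n = 4 per group, adjusted p = 7.72e-06), at 7.68 ± 0.12 (SD) against 4.47 ± 0.35 in A/J, a level near the lower quartile of the arrays (4.46 to 4.60) that was not shown to be above background. Erdr1 was 9.06-fold lower (-3.18 ± 0.32, adjusted p = 4.32e-06) and Baiap2l1 4.56-fold lower (-2.19 ± 0.13, adjusted p = 1.29e-08). Mog, myelin oligodendrocyte glycoprotein, was lower in DBA/2J (-1.42 ± 0.18, adjusted p = 6.28e-05), and so was Cx3cr1, the fractalkine receptor of microglia (-1.05 ± 0.14, adjusted p = 8.8e-05). Egr2 was higher in DBA/2J (0.64 ± 0.13, adjusted p = 0.0054; 0.50 ± 0.16, adjusted p = 0.244 with 3 regional marker scores as covariates), Klf2 lower (-0.78, adjusted p = 7e-05), and Fos at 0.35 (adjusted p = 0.0569) did not pass except without DBA/2J risperidone replicate 1 (0.0444) or 4 (0.0425).

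With limma 908 genes passed, 397 with a probe set higher and 525 with one lower in DBA/2J and 14 with both, from 1745 probe sets of which 708 name no gene. The median absolute log2 difference of these probe sets was 0.505. Of 1132 other probe sets of called genes, 817 (72.2%) had the same sign, and of 583 called genes with several probe sets 95 (16.3%) had another called in the same direction. Most calls therefore rest on a single probe set. Whether the strain differences, those of the strain markers included, reflect RNA levels or sequence differences between the strains at the probes was not tested. Without A/J control replicate 3 the count was 553. Higher genes included Bub1 (2.79), a mitotic checkpoint kinase, Pisd-ps3 (2.53), Stab2 (2.43), Sfi1 (2.23), Pisd (1.99), Cldn34c1 (1.57), Phkg1 (1.36), Mael (1.34) and Zfp949 (1.30). Lower genes included the noncoding RNAs Gas5 (-2.11) and Neat1 (-1.97), Tnnt2 (-1.86), Catspere2 (-1.67), Krt12 (-1.62), Sbsn (-1.5) and Ier5 (-1.5). Each of the 20 genes passed without each array in turn, and Sbsn missed with 3 regional marker scores as covariates (-1.22 ± 0.27, adjusted p = 0.0589). Among genes known to carry variants in these strains, Myo5a, the dilute coat colour gene mutated in DBA/2J, was lower (-0.41 ± 0.09, adjusted p = 0.0129; -0.38 ± 0.14, adjusted p = 0.348 with regional marker scores; -0.32, adjusted p = 0.0220 without DBA/2J control replicate 4, where its level was lowest), while Gpnmb (-0.03, adjusted p = 0.933), Klrd1 (0.12, adjusted p = 0.687) and Dysf (-0.17, adjusted p = 0.335) did not pass.

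Cell type lists separated the strains in control mice. Microglia markers were lower in DBA/2J in 13 of 14 members (median -0.29, adjusted p = 5.0e-06; adjusted p = 0.0271 with an estimated correlation), of which 2, Cx3cr1 and P2ry12 (-0.38, adjusted p = 0.013), passed over all genes and 7 were lower adjusted over the list alone. Oligodendrocyte markers were lower in 15 of 16 (median -0.34, adjusted p = 3.5e-07; adjusted p = 0.633 with an estimated correlation), 2 over all genes and 9 adjusted over the list alone. With 3 regional marker scores as covariates the oligodendrocyte call was lost (median -0.09, adjusted p = 0.323; range over its alternatives 2.8e-10 to 0.633), and 132 genes passed in all. Mog (-1.10 ± 0.24, adjusted p = 0.0594) and Cx3cr1 (-0.87 ± 0.21, adjusted p = 0.0887) then missed with smaller differences and larger SE, and P2ry12 was at -0.22 ± 0.12 (adjusted p = 0.547). Mag, the other oligodendrocyte marker called (-0.86 ± 0.23), was then at -0.43 ± 0.28 (adjusted p = 0.626). It also missed without 6 of the 16 arrays, at adjusted p up to 0.142, and with the replicate number as a block (adjusted p = 0.0572). Thalamus markers were lower in 7 of 7 (median -0.52, adjusted p = 0.00507; adjusted p = 0.633 with an estimated correlation), none over all genes and 4 adjusted over the list alone, and this call was lost without A/J control replicate 3 (median -0.34, adjusted p = 0.153). Tcf7l2, a member, was at -1.18 (adjusted p = 0.195), at -1.65 without A/J control replicate 2 (0.0464) and at -0.60 without A/J control replicate 3 (0.496). Dopamine signalling genes were lower in 16 of 21 (median -0.17, adjusted p = 0.0389; adjusted p = 0.633 with an estimated correlation). 1 of them, Ppp1r1b, which encodes DARPP-32 (-0.61, adjusted p = 0.0443), passed over all genes and adjusted over the list alone; it missed without 11 of the arrays, at adjusted p up to 0.146, and with 3 regional marker scores as covariates (-0.48 ± 0.21, adjusted p = 0.434). The dopamine call was lost without A/J control replicate 3 (adjusted p = 0.216), DBA/2J control replicate 2 (0.0744) or 4 (0.160).

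Ribosomal protein genes were lower in DBA/2J control mice in 58 of 63 (median -0.14, adjusted p = 8.2e-05), with 3 lower and 1, Rpl14 (1.09, adjusted p = 1.8e-05), higher over all genes and adjusted over the list alone. Oxidative phosphorylation genes were lower in 39 of 44 (median -0.13, adjusted p = 0.00035) and choroid plexus and ependyma markers in 11 of 13 (median -0.16, adjusted p = 0.0291), with Ttr at -2.88 (adjusted p = 0.19). These 3 calls were lost at adjusted p = 0.847 with an estimated correlation in each. Without DBA/2J control replicate 4, whose ribosomal level was low, the ribosomal median turned to 0.00083 (adjusted p = 0.945) and that of oxidative phosphorylation -0.02 (adjusted p = 0.612). The choroid plexus call was lost without A/J control replicate 1 (adjusted p = 0.258) and without DBA/2J control replicate 1 (0.0719), 2 (0.0688) or 3 (0.0955).

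The strains were compared again after risperidone. Pdxdc1 was higher in DBA/2J (log2 difference 1.79 ± 0.33 SE, n = 4 per group, adjusted p = 0.0107), at 7.74 ± 0.07 (SD) against 5.95 ± 1.09 in A/J, and missed with trend and robust options (adjusted p = 0.0569) and with 3 regional marker scores as covariates (1.40 ± 0.31, adjusted p = 0.0697). Erdr1 was 6.52-fold lower (-2.71 ± 0.32, adjusted p = 0.000103) and Baiap2l1 3.59-fold lower (-1.84 ± 0.13, adjusted p = 1.84e-07). Cx3cr1 was again lower (-0.78 ± 0.14, adjusted p = 0.0062; -0.69 ± 0.16, adjusted p = 0.0734 with regional marker scores), and Serpina3n, an acute phase protease inhibitor gene of reactive astrocytes, was higher (0.97 ± 0.20, adjusted p = 0.0223).

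With limma 175 genes passed, 89 with a probe set higher and 88 with one lower in DBA/2J and 2 with both, from 352 probe sets. The strain calls in risperidone mice shared 135 higher and 168 lower probe sets with those in control mice, against 3.16 and 3.63 expected, with 0 in opposite directions. In this comparison 3 of the 4 A/J arrays, replicates 1, 2 and 4, had intermediate strain markers. Without these 3 arrays, which leaves 1 A/J array (replicate 3) and takes the spread from the other groups, the differences were 3.38 for Pdxdc1, 2.58 for Pisd-ps3, 2.18 for Sfi1, 2.00 for Pisd, 1.40 for Phkg1 and 1.40 for Zfp949, over 1.5 times those with all arrays. Without them Cx3cr1 (-0.89 ± 0.23, adjusted p = 0.147), Serpina3n (1.29 ± 0.32, adjusted p = 0.127), Mael (0.92 ± 0.27, adjusted p = 0.279) and Sspn (-1.25 ± 0.27, adjusted p = 0.0595) missed, and without 5 arrays in doubt Sox2ot was at 1.32. With 3 regional marker scores Pisd-ps3 (1.17 ± 0.27, adjusted p = 0.0755), Serpina3n (0.93 ± 0.23, adjusted p = 0.123) and Mael (0.83 ± 0.18, adjusted p = 0.0548) missed. The count was 85 without A/J risperidone replicate 3, 103 without A/J risperidone replicate 1 and 293 without DBA/2J control replicate 4. Further higher genes were Pisd-ps3 (1.35), Pisd (1.27), Sfi1 (1.21), Rpl14 (0.92), Phkg1 (0.91), Zfp949 (0.89), Sox2ot (0.87) and Mael (0.87), and lower ones Gas5 (-1.66), Catspere2 (-1.53), Tnnt2 (-1.42), Neat1 (-1.41), Sbsn (-1.31), Ier5 (-1.22), Sspn (-0.97) and Slc5a5 (-0.94). Serpina3n missed without A/J risperidone replicate 1 (adjusted p = 0.0701), 2 (0.0596) or 3 (0.113) and DBA/2J risperidone replicate 1 (0.0998) or 3 (0.0925), Mael without A/J risperidone replicate 1 (0.0512) and Sspn without A/J risperidone replicate 3 (0.0600).

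Microglia markers were lower in DBA/2J risperidone mice in 11 of 14 (median -0.14, adjusted p = 0.00085; adjusted p = 0.112 with an estimated correlation), 1 over all genes and 3 adjusted over the list alone. Thalamus markers were lower in 7 of 7 (median -0.27, adjusted p = 0.0232; adjusted p = 0.784 with an estimated correlation), none over all genes or adjusted over the list alone. Early genes were lower in 20 of 32 (median -0.07, adjusted p = 0.00314; adjusted p = 0.444 with an estimated correlation), 2 over all genes and 2 adjusted over the list alone. The thalamus call was lost without A/J risperidone replicate 3 (adjusted p = 0.188) and without DBA/2J risperidone replicate 1 (0.0963), 2 (0.0917) or 3 (0.0831), and the early gene call without DBA/2J risperidone replicate 1 (0.0824). Without the 3 A/J risperidone arrays with intermediate strain markers, with 1 A/J array left, the early gene median was -0.02 (adjusted p = 0.370), and without 5 arrays in doubt it turned to 0.02 (adjusted p = 0.837).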

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

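Tests chosen only after the result was seen were all those on the intermediate strain markers, both on the lower early genes and that on a low share of striatum; the other tests on choroid plexus and thalamus markers and all tests with other splits of the arrays were set beforehand.

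Strain markers were intermediate in 3 of the 4 A/J risperidone arrays (shares of 28.5%, 36.5% and 39.7%). The shares cannot decide on first-generation hybrid mice, although all 3 lay below 50%, with a highest upper limit of 45.8%. The intervals cover markers only and can miss the value of the labelled strain. That of A/J control replicate 2 was -5.79% to -0.996%, wholly under 0. That of DBA/2J risperidone replicate 1 was 83.2% to 90.7%, under the lowest DBA/2J control share (96.0%). A simulated share of 30% was recovered as 24.1% to 37.3%. A/J risperidone replicate 1 lay farthest from 50%, with an upper limit of 32.8%. Mice carrying some chromosomes of the other strain stay open. Under 10% lay 3 of 33 chromosome medians, where 9.97 would be free of the other strain's copy (binomial p = 0.00389). That test cannot decide, because it takes the same 11 chromosomes in 3 arrays as independent. Only 19 of the 49 markers were placed, and most chromosomes had a single marker. A candidate explanation that stays open is DBA/2J tissue or RNA mixed into these samples, as shares from markers high in DBA/2J were above those from markers high in A/J by 6.13, 6.37 and 11.5 percentage points, with wide 95% intervals that include 0 in each array (up to 20.1). For a drug response that differs from gene to gene, the spread over markers decides nothing. It was 12.3, 8.16 and 13.4 percentage points in these arrays, against 6.65 to 11.2 in A/J control arrays and 5.68 to 14.2 in all control arrays. In all 3 arrays both marker sets moved toward DBA/2J. Shares were 29.2%, 37.6% and 42.1% from markers high in DBA/2J, and 23.1%, 31.2% and 30.5% from markers high in A/J. Replicate 3, given the same drug, lay at 0.283%. These values argue against such a response as the whole cause in the 3 arrays. Whether mice of mixed descent other than these or an even drug response over all markers gave the same values was not tested.

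Early genes were lower after risperidone in both strains as a list, though in A/J the adjusted p was 0.133 with an estimated correlation and no member passed over all genes. A mixture with tissue or RNA of DBA/2J control mice is argued against as the whole cause in A/J. From each array's share and the control means, the predicted difference was 0.020 at the median against -0.149 seen. The median of seen minus predicted was -0.192 (95% interval -0.288 to -0.0747, which takes genes as independent). A mixture with DBA/2J risperidone mice was not tested. Their mean early gene level was lower, at 7.01 against 7.31 in DBA/2J control mice. Different amounts of choroid plexus or thalamus are argued against as the whole cause. With the 3 regional marker scores as covariates the list's median over both strains was -0.195 (camera, adjusted p = 9.1e-19). For the amount of striatum this cannot decide, because striatal projection neuron markers did not deviate together within groups (mean correlation 0.032). Cortex markers were not a covariate, so a different amount of cortex was not tested. A lower activity of these genes after the drug may account for the difference, as a hypothesis found and tested on the same data. Handling, the time from injection to dissection and the order of dissection were not tested.

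Choroid plexus and thalamus markers varied between arrays of 1 group. Within groups lay 66.5% of the variance of the choroid plexus score and 68.9% of that of the thalamus score, which restates the variation and tests no effect of the groups. Different amounts of neighbouring tissue in the dissections could account for it: members deviated together, with a mean correlation of 0.466 for choroid plexus markers (highest of 10000 random lists 0.270) and 0.674 for thalamus markers (highest 0.476). Striatal projection neuron markers (0.032, percentile 54.7 of the random lists) and cortex markers (0.192, percentile 83.0) did not stand out. Whether all samples hold a low share of striatum cannot be told apart from normal levels, because no pure striatum sample was used for comparison and signals of different probe sets are not comparable, so the level of Drd2 (percentile 17.2) decides nothing. Cortex markers had a median percentile of 93.0, and all 8 lay between 81.9 and 98.0. The median percentile was 84.1 for striatal projection neuron markers (40.3 to 99.2). It was 72.5 for indirect-pathway and 56.5 for direct-pathway neuron markers. Signal of cortex markers was thus high in these samples, and the results may not describe striatum alone. The share of cortex in the samples was not tested. No biological explanation was tested.

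Of 504 groups of 4 values tested, 35 held a value far from the other 3 (its gap to the nearest, divided by the range of the 4, above the 95% critical value of Dixon's test), where chance gives about 1 in 20 groups (25.2), and 11 of the 35 were DBA/2J control replicate 4. In that array the gap was 1 for the median log2 level (5.71 against 5.68), 0.895 for the mean correlation within the group (0.978 against 0.988 to 0.989) and 0.839 for the SD of deviations (0.273 against 0.139 to 0.161). It was 0.871 for the ribosomal protein score (10.04 against 10.49 to 10.56), 0.925 for oxidative phosphorylation (9.52 against 9.93 to 9.96) and 0.866 for neuropeptides (6.64 against 6.85 to 6.88). It was 0.893 for Klf2 (6.35 against 6.60 to 6.63) and for Drd1 (5.85 against 6.10 to 6.13), 0.872 for Myo5a (8.95 against 9.29 to 9.34), 0.855 for Tac1 (5.91 against 6.62 to 6.74) and 0.929 for Pcolce2 (5.93 against 6.06 to 6.07).

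Values of the other arrays, in both strains, stood apart no more often than chance gives, so they single out no array. In DBA/2J they were the following. DBA/2J risperidone replicate 4 had a gap of 0.901 for dopamine signalling (7.40 against 6.96 to 7.01), 0.850 for thalamus markers (6.39 against 5.64 to 5.75) and 0.833 for Rptor (6.82 against 6.64 to 6.67). Replicate 3 had one of 0.904 in control mice (8.10 against 8.03) and 0.901 in risperidone mice (8.15 against 8.04 to 8.05) for glutamate signalling. DBA/2J risperidone replicate 1 had one of 0.844 for choroid plexus and ependyma markers (5.88 against 4.75 to 4.93). DBA/2J risperidone replicate 2 had one of 0.885 for Dusp1 (9.57 against 9.31 to 9.34), 1 for Zc3h6 (5.37 against 5.30) and 0.889 for Ttc39c (6.68 against 6.92 to 6.95), and DBA/2J control replicate 2 one of 0.833 for Baiap2l1 (6.27 against 6.15 to 6.17).

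In A/J, control replicate 2 had a gap of 1 for the median log2 level (5.68 against 5.66), 0.833 for Dusp1 (9.68 against 9.78 to 9.80), 0.846 for Slc47a1 (4.81 against 4.03 to 4.15) and 0.878 for Pisd (6.59 against 6.95 to 7.00). A/J control replicate 3 had one of 0.948 for astrocyte markers (8.59 against 8.43 to 8.44) and 0.844 for interferon response and MHC class I genes (5.19 against 5.24 to 5.25), and A/J control replicate 4 one of 0.898 for vascular cell markers (6.63 against 6.73 to 6.74). A/J risperidone replicate 1 had one of 0.833 for Vmn2r29 (6.04 against 6.34 to 6.40), 0.889 for Dysf (5.67 against 5.40 to 5.43), 0.958 for Dusp1 (9.68 against 9.44 to 9.45) and 0.839 for Baiap2l1 (8.28 against 7.97 to 8.02). A/J risperidone replicate 3 had one of 0.851 for Pisd-ps3 (6.88 against 8.37 to 8.63) and 0.903 for Akt2 (7.80 against 8.08 to 8.11), and A/J risperidone replicate 4 one of 0.870 for Ttr (7.38 against 11.27 to 11.85).

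The risperidone effect differed between the strains, by the interaction test with the preset correlation, for 4 lists: ribosomal protein genes (0.145), oxidative phosphorylation genes (0.165), oligodendrocyte markers (0.313) and early genes (-0.104). None of these passed with an estimated correlation (adjusted p = 0.757 with an estimated correlation in each).

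Other splits of the same arrays were counted for each comparison. For risperidone the true split alone reached its count in DBA/2J (11 genes, in 1 of 35 splits, the fewest possible, highest other 7). The same held over both strains (9 genes, in 1 of 100, highest other 0). It also held for strain in control mice (908 genes, in 1 of 35, highest other 0) and in risperidone mice (175 genes, in 1 of 35, highest other 0). With so few splits this does not exclude chance, least of all in DBA/2J. In the strain comparisons the other splits mix both strains in a group, which widens the spread, so few genes could pass there in any case. The count in DBA/2J did not hold in other settings: without single arrays it lay between 2 and 27, and with only the 8 arrays compared or 5 arrays left out it was 0. For risperidone in A/J (0 genes, highest other 5) and the interaction (0 genes, highest other 1) the count of splits tests nothing, because every split reaches a count of 0 (35 of 35 and 100 of 100).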

How the results depend on the processing

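The alternatives with the DBA/2J share or regional scores as covariates, with 3 or 5 arrays in doubt left out and with probe sets called for strain left out were added after seeing the data; the rest were planned. Of 174 comparisons of a count with an alternative, 116 lay within 1.5 times the first value and 58 did not. Applying quantile normalization again, median centring, at least 1.2-fold and the replicate block left all 6 counts within 1.5 times. With the block they were 0, 12, 12, 0, 926 and 180, though the risperidone calls of Dusp1, Rell1 and Btg2 were lost. The call of Mag between strains in control mice was lost too. Genes called for risperidone in A/J (0) were 7 among probe sets above the median level, 12 with array weights and 1 with only the 8 arrays compared, 3 arrays left out or 5 left out. In DBA/2J (11) they were 23 above the median level, 17 with trend and robust options, 5 with array weights, 0 with only the 8 arrays compared, 3 with the share covariate, 1 with regional covariates, 2 with 3 and 0 with 5 arrays left out, and 1 without probe sets called for strain. Over both strains (9) they were 14 above the median level, 3 with the share, 2 with regional covariates, 0 with 3 and 2 with 5 arrays left out. For the interaction (0) there was 1 with 3 arrays left out. Between strains in control mice (908) they were 596 with 1 probe set per gene, 447 with only the 8 arrays compared, 132 with regional covariates, 576 with 3 and 605 with 5 arrays left out. In risperidone mice (175) they were 101 with 1 probe set per gene, 337 with array weights, 99 with regional covariates and 97 with 3 arrays left out. Settings with 3, 5 or 8 fewer arrays or with 1 probe set per gene hold fewer arrays or probe sets by construction; for the other settings the cause was not tested.

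Leaving out each array in turn gave 0 to 17 genes in A/J, 2 to 27 in DBA/2J, 4 to 17 over both strains, 0 to 7 for the interaction, 553 to 919 between strains in control and 85 to 293 in risperidone mice. The mTOR list's median then lay between -0.025 and 0.0083 in A/J, 0.011 and 0.051 in DBA/2J and -0.01 and 0.065 for the interaction, where array weights gave -0.022 (first value 0.02; the cause was not tested); the other 83 of 84 comparisons of the mTOR lists were unchanged in call and direction or moved by less than the spread. The early gene list passed in DBA/2J and over both strains under every alternative run, and in A/J under all but the estimated correlation; with 3 or 5 arrays left out, 1 A/J risperidone array remains, so those 2 settings say little about A/J.

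The ribosomal list in A/J turned to -0.079 with the share covariate (adjusted p = 0.0309) from 0.0025 (adjusted p = 0.741). Between strains in control mice it turned to 0.00083 without DBA/2J control replicate 4 (lowest without 1 array -0.19) and with 5 arrays left out, which include that array. Oxidative phosphorylation over both strains turned to -0.0067 without that array (highest without 1 array 0.060) and -0.0023 with 5 left out. The early gene list between strains in risperidone mice turned to 0.023 with 5 arrays left out. The cause was not tested. Of 4706 comparisons of other lists, 4474 were unchanged in this sense, 106 lost a call, 68 gained one, 6 turned and 52 moved; of 6587 of named genes, 6242, 266, 54, 0 and 25. The 1.2-fold and 8-array settings were run for counts alone, the 8-array setting is not defined for the interaction or the mean over strains, the share covariate was fitted for risperidone comparisons because it runs with strain, and regional lists were not tested with themselves as covariates. Low array signals, such as that of Drd2, limit what differences could be seen.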

Other observations

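Some genes of lists that did not pass as a whole differed between the strains in control mice. Of 53 mTOR signalling genes 3 were lower in DBA/2J over all genes, and adjusted over the list alone 3 were lower and 2 higher; among them Rragd, a GTPase gene of amino acid sensing, was at -0.43 ± 0.09 (SE, n = 4 per group, limma adjusted p = 0.00985) and Prr5l at -0.86 (adjusted p = 0.0203). Of 19 striatal projection neuron markers 14 were lower (median -0.10, adjusted p = 0.0589), 3 over all genes, and adjusted over the list alone 5 were lower and 1 higher. Pde10a, a phosphodiesterase gene of striatal projection neurons, was lower (-0.43, adjusted p = 0.0247), and so was Gfap, the intermediate filament gene of astrocytes (-0.42, adjusted p = 0.0148). Of 15 neuropeptide genes 3 were higher and 1 lower, over all genes and adjusted over the list alone.

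Prr5l missed without A/J control replicate 1 (adjusted p = 0.0700) or 3 (0.0723) and DBA/2J control replicate 1 (0.0571) or 3 (0.0544). Pde10a missed without A/J control replicate 2 (0.0728) or 3 (0.0712) and DBA/2J control replicate 1 (0.0621) or 4 (0.0627), and Gfap without A/J control replicate 3 (0.0525). With 3 regional marker scores as covariates, added after seeing the data, none of the 4 passed: Rragd (-0.22 ± 0.11, adjusted p = 0.520) and Prr5l (-0.33 ± 0.26, adjusted p = 0.695) had differences smaller by over 1.5 times, while Pde10a (-0.48 ± 0.16, adjusted p = 0.272) and Gfap (-0.31 ± 0.15, adjusted p = 0.463) differed by less than that from their first values and had larger SE; the lowest adjusted p over the alternatives of each was 0.00288, 0.00328, 0.0124 and 0.00667.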
